A study of Mus musculus with 12 samples.

How the data were processed

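RNA from 12 mouse samples was measured on Affymetrix mouse genome arrays, with 1 array per sample. Per the labels, total RNA was extracted with Trizol, amplified with an Affymetrix target labelling kit and hybridised as biotin-labelled cRNA. The deposited values are probe set intensities on the linear scale. The submitters' processing notes name RMA, the robust multi-array average, and give no version; array scanner files were not used here. Because RMA gives log2 values, the intensities deposited by the authors had been turned back to the linear scale, and log2 was taken again before each test. The medians of the 8 arrays on the T cell side (DP thymocytes, T lymphoma and the cell line) lay between 99.5 and 109, and those of the 4 arrays on the stem cell side (HSC and LSC) between 44.3 and 46.1. The arrays of each side therefore looked normalized apart from the other side. Every contrast was made within a side, the interaction is a difference of 2 such contrasts, and levels set across the sides carry this offset. Arrays hold no read depth; the number of arrays limits the precision.

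The table held 45101 probe sets, of which 64 were array controls. A platform annotation gave 34958 probe sets 1 gene symbol and 932 several symbols, and left 9160 unnamed here, while 13 of the controls also had a symbol and stayed out; probe sets with several or no symbols stayed out of the gene tests. Of the named probe sets, 34754 matched a RefSeq gene through the Entrez identifier, and 0 symbols changed. No genome build is named in the sources used here, so no coordinates are given. Each of 18193 genes was represented by its probe set with the highest mean over the 12 arrays, and 12797 genes were tested after a filter that kept a gene above log2 6.33 (the median of all values, an intensity of 80.2) in at least 2 arrays. This rule can keep a probe set that other probe sets of the gene do not follow. Of the 838 genes called between T lymphoma and DP thymocytes, 417 had other tested probe sets. In 0 of these was another probe set called in the opposite direction, and in 190 no other was called. Of the 1313 genes called between LSC and HSC, 632 had other tested probe sets, with 2 opposite calls (Mycn among them) and 374 in which no other was called. In the other 3 contrasts 0 opposite calls were found, and no other probe set was called in 306 of 538 genes for the difference of the contrasts, 43 of 61 for the cell line and 25 of 37 for the sorted lymphoma.

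Groups were taken from the labels: 3 arrays of sorted DP thymocytes, 4 of T lymphoma (3 unsorted, 1 sorted), 1 of the ZNF112 cell line, 2 of HSC and 2 of LSC. The labels call the replicates biological, and several were pools of mice. Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values, two-sided). The fit had a mean for each group over the 12 arrays, so that all groups shared 1 estimate of the spread, and a Benjamini-Hochberg adjusted p under 0.05 counted as a call. The shared spread is a compromise: the root mean square SD over genes was 0.153 in DP thymocytes, 0.619 in T lymphoma, 0.554 in HSC and 1.01 in LSC. The 5 contrasts were T lymphoma minus DP thymocytes, LSC minus HSC, the difference of these contrasts, the cell line minus T lymphoma, and the sorted minus the unsorted lymphomas. For the last contrast the sorted array was a group of its own. A lone array was assumed to vary like the other groups. Overlaps of calls were tested with Fisher's exact test; the overlapping comparisons share no arrays but share the estimate of the spread.

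The 26 gene lists, the genes to name and all alternatives except 1 were fixed before the data were examined. The lists cover Notch pathway members and targets, the T cell receptor complex, genes of double-positive thymocytes, T lineage factors, early T and progenitor regulators, stem cell markers, lymphoid priming, feedback genes of receptor tyrosine kinase signalling and STAT5 targets. They also cover DNA replication, mitosis, MYC targets and ribosome biogenesis, glycolysis, BCL2 family genes, CDK inhibitors and tumour suppressors, MHC class I presentation, interferon response, homing and adhesion, and immediate early genes. Markers of granulocytes, macrophages, B cells, erythroid cells, NK and cytotoxic cells, stroma and endothelium, and megakaryocytes stood for other cell types. The lists named 355 genes, of which 327 had a named probe set here and 318 were tested; the others, such as Lck, Tcf7 and Trp53, were not analysed here. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 26 lists of a comparison. They were also tested with an estimated correlation and with fry. A list is called higher or lower by its camera test; fry tests the direction of the members on balance and does not compare them with other genes. With an estimated correlation, 0 of the 26 lists passed in any of the 5 comparisons.

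Named genes followed a rule. For T lymphoma against DP thymocytes and LSC against HSC, the 10 genes with the largest rise and the 10 with the largest fall among calls with non-overlapping groups were taken. For the other contrasts, 5 were taken each way. From each list came up to 4 called members with the largest change, or the 2 with the largest change as values. In addition, 20 genes were always reported, of which 19 were measured. Control probe sets at the 3' and 5' ends of the beta-actin and Gapdh transcripts were compared in each array as a sign of RNA quality.

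The procedure was tested on simulated data with the real gene means and spreads: 12797 genes, of which 200 changed, 100 by 1 and 100 by 2 on the log2 scale, in 10 runs. With an equal spread, on average 76.0 of the 100 genes changed by 2 and 18.9 of those changed by 1 were found for T lymphoma against DP thymocytes, with 6.40 false calls. For LSC against HSC, 52.8 and 3.30 were found, with 2.80 false calls. With each group given its own measured spread, false calls rose to 119 for LSC against HSC, were 1 for T lymphoma against DP thymocytes, and were 6.80 each for the cell line and for the sorted lymphoma. The cell line, with 1 array, has no measured spread and kept the shared one. The sorted lymphoma was given the spread of the T lymphoma group. For LSC against HSC in that setting, 62.1 and 18.2 of the changed genes were found, together fewer than the false calls. Of its unchanged genes, 15.1% had an unadjusted p under 0.05. A list of 20 genes shifted by 1 was called in 10 of 10 runs of the simulated T lymphoma comparison, and 1 of 260 unchanged lists was called. In these list runs the genes varied independently of each other and with an equal spread. The count of unchanged lists called therefore gives no error rate for lists of correlated genes. Alternatives were a fit on only the arrays compared, the replicate number as a block, the mean of all probe sets, every probe set alone, no _x_at and _s_at probe sets, no filter, a filter at the 75th percentile, cyclic loess, median centring, trend and robust moderation, array weights, leaving out each array, and an estimated correlation. The lymphoma contrast with only the sorted array was chosen after seeing the data. Figures were drawn with matplotlib in Python.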

Results

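The arrays profile a mouse model in which the ZMYM2-FGFR1 fusion kinase drives T cell lymphoma. Transplanted T lymphomas (n = 4; 3 unsorted tumours that were mostly GFP+ Thy1+ double-positive cells, 1 tumour sorted for such cells) were set beside sorted normal CD4+CD8+ double-positive (DP) thymocytes (n = 3). Leukaemic stem cells (LSC; GFP+ lineage-negative Sca-1+ c-Kit+ cells from bone marrow or spleen of diseased mice, n = 2) were set beside haematopoietic stem cells of the same surface phenotype from normal marrow (HSC, n = 2). The last array held ZNF112, which the labels describe as a cell line (n = 1).

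Arrays of the same group resembled each other to different degrees. Across the 12797 genes tested, the mean Pearson correlation between arrays was 0.995 among DP thymocytes, 0.920 among T lymphomas, 0.940 between the HSC arrays and 0.796 between the LSC arrays; genes are not independent replicates. T lymphoma and DP thymocytes correlated at 0.877 on average, the cell line at 0.887 with T lymphoma and 0.884 with DP thymocytes, and LSC at 0.811 with HSC. The LSC arrays stood apart. LSC 2 correlated at 0.869 to 0.897 with the 4 lymphomas, at 0.866 with the cell line and at 0.841 to 0.844 with DP thymocytes. It correlated at 0.791 and 0.801 with the HSC arrays and at 0.796 with LSC 1. LSC 1 correlated at 0.818 and 0.833 with HSC, at 0.720 to 0.795 with the lymphomas, at 0.711 with the cell line and at 0.704 to 0.715 with DP thymocytes. The 3' over 5' ratio of beta-actin, which rises with RNA degradation or short amplification products, was 2.18 to 2.23 in DP thymocytes and 2.44 to 3.69 in T lymphoma. It was 3.91 and 5.79 in HSC and 9.82 and 13.6 in LSC.

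**Figure D1:**
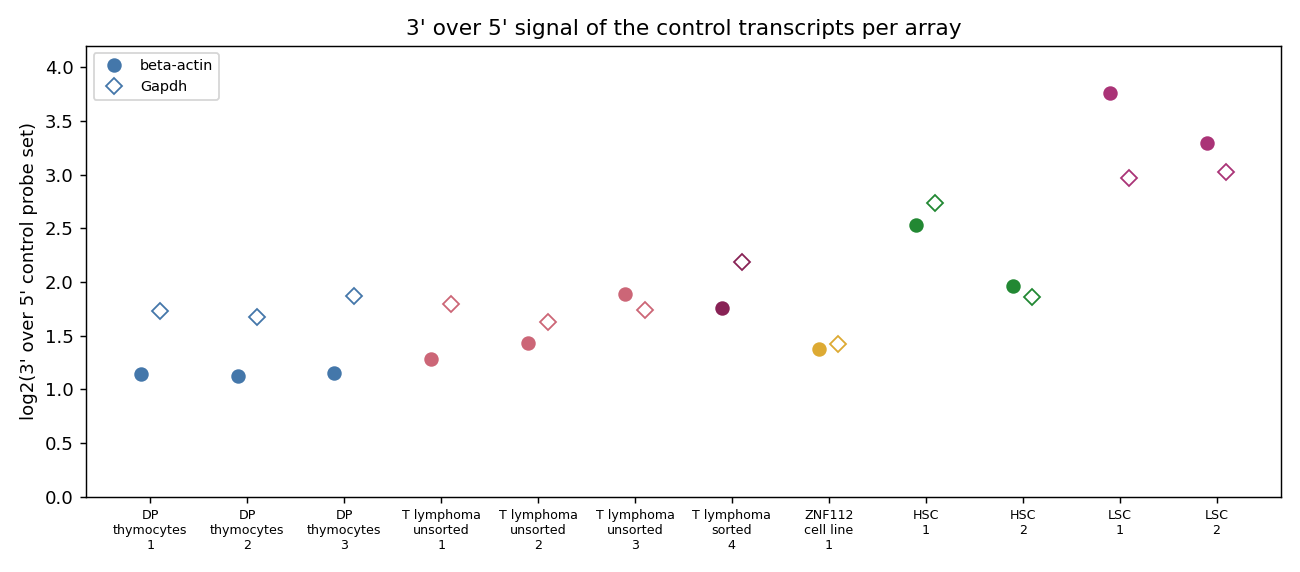
Signal of the 3' over the 5' control probe set on the log2 scale for beta-actin (filled circles) and Gapdh (open diamonds), 1 column per array, coloured by group. The LSC arrays stand highest for beta-actin, at 3.76 and 3.30, against 1.13 to 1.16 in DP thymocytes.

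T lymphoma was compared with DP thymocytes to see how the tumours differ from the normal cells with the same surface markers. Large rises were seen in the T cell receptor gamma variable genes Trgv1 (log2 difference 8.50 ± 0.28 SE) and Trgv4 (8.34 ± 0.33), and in Il2ra, the alpha chain of the interleukin-2 receptor (7.17 ± 0.21). Ctla4, an inhibitory T cell receptor, rose by 6.98, the inflammatory caspases Casp4 and Casp1 by 6.96 and 6.26, and the interferon-inducible GTPase Iigp1 by 6.88. Cd5 and Cd6, surface receptors that restrain T cell receptor signalling, were lower by -6.82 ± 0.33 and -5.17 ± 0.24. In all, 431 genes rose and 407 fell among 12797 (limma, Benjamini-Hochberg adjusted p under 0.05), 392 and 324 of them by 2-fold or more. Ddc, Plac8 and Drc1 rose as well: Ddc, which encodes dopa decarboxylase, by 6.99, Plac8 by 6.75 and Drc1 by 6.21. Other large falls were in Bex1 (-6.12), Tdrp (-5.98), Ugt8a (-5.26), Dgkeos (-4.75), Arap2 (-4.48), Nhsl1 (-4.28), Egr1 (-4.06), a transcription factor induced by receptor signalling, and E2f2 (-4.04), an E2F family factor. For 9 of these 20 genes (Trgv1, Trgv4, Ddc, Casp4, Casp1, Bex1, Tdrp, Ugt8a and Dgkeos) every array of the lower group lay under the filter level of log2 6.33, so the size and order of their changes are uncertain, as is the size for Socs2 below. Il2ra, Ctla4, Iigp1 and Drc1 reached only 6.57, 6.34, 6.42 and 6.48 in DP thymocytes, so their sizes rest on low values too. The level, an intensity of 80.2, lies below the array medians of this side (99.5 to 109). It lies above those of the stem cell side (44.3 to 46.1), so counts of genes under it are not alike between the sides. Other tested probe sets of Ddc (0.88, called), Ugt8a (-0.60) and Nhsl1 (-0.24) changed far less, the last 2 without a call.

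Of 19 measured Notch pathway members and targets, 6 rose and 1 fell, and 9 and 3 did so when adjusted over the list alone. Dtx1, a Notch target that encodes Deltex, rose by 4.92 ± 0.38 to a log2 intensity of 13.1 ± 0.76 (SD, n = 4), Notch3 by 2.69 ± 0.29, Notch1 by 1.64 ± 0.21, Ptcra, the pre-T cell receptor alpha chain, by 2.27 ± 0.50 and Myc by 2.26 ± 0.26. Another tested probe set of Dtx1 did not pass, at -0.21 (limma, Benjamini-Hochberg adjusted p = 0.727). Ccnd3, a D-type cyclin, fell by 2.51. Hes1 and Nrarp, further Notch targets, had differences of 1.61 and 1.58 that did not pass (limma, Benjamini-Hochberg adjusted p = 0.169 and 0.187). The list was higher by camera (adjusted p = 3.56e-04, and adjusted p = 0.212 with an estimated correlation). Among 12 STAT5 targets, 8 rose and 2 fell, the same counts when adjusted over the list alone. Il2ra, which both lists hold, Socs2 (4.65) and Cish (4.16), feedback inhibitors of cytokine signalling, rose, while Bcl6, a repressor that STAT5 is known to turn down, fell by 3.85. Bcl2l1, also held by the list, was the other member that fell, at -1.39. The STAT5 list was higher (camera adjusted p = 2.10e-05, and adjusted p = 0.248 with an estimated correlation).

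**Figure D2:**
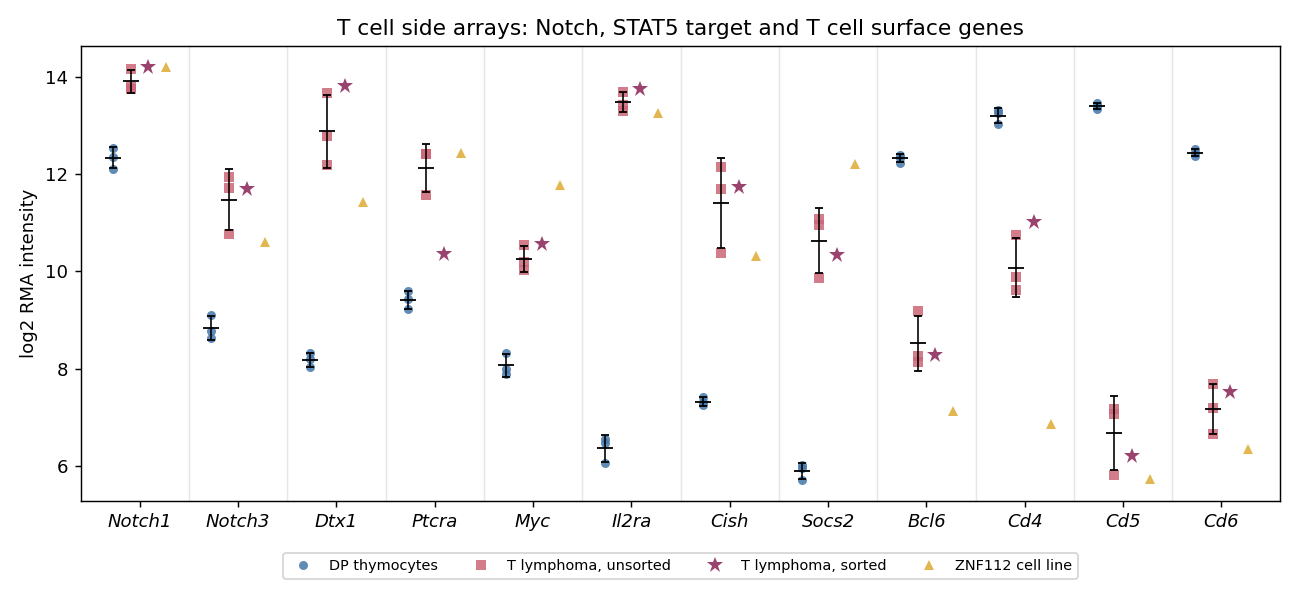
Log2 RMA intensity (vertical axis) of 12 genes in each array of the T cell side: DP thymocytes (circles, n = 3), unsorted T lymphoma (squares, n = 3), sorted T lymphoma (star, n = 1) and the ZNF112 cell line (triangle, n = 1); bars are mean and SD. Il2ra lies between 13.3 and 13.7 in the 4 lymphomas and between 6.06 and 6.57 in DP thymocytes.

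Some genes of the normal DP stage were lower. Of 15 measured members of the double-positive list, 0 rose and 4 fell (0 and 6 when adjusted over the list alone): Cd4 by 2.88 ± 0.40, the chromatin organiser Satb1 by 1.62, Arpp21 by 1.39 and the recombinase gene Rag1 by 0.76. Cd8a and Thy1 had differences of -1.30 and -1.07 (limma, Benjamini-Hochberg adjusted p = 0.253 and 0.422). The list was lower (camera adjusted p = 1.80e-05, and adjusted p = 0.248 with an estimated correlation). In the T cell receptor list, Cd5 and Cd6 fell and 13 of 15 members did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 2.46e-04, and adjusted p = 0.388 with an estimated correlation). Among 14 T lineage factors, Runx3 rose by 3.33 and 5 fell (1 and 7 when adjusted over the list alone), with Egr1, E2f2 and Egr2 (-2.99) changing most (camera adjusted p = 9.96e-05, and adjusted p = 0.248 with an estimated correlation).

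Lists of antigen presentation and interferon genes were higher. Of 10 MHC class I presentation genes, 6 rose (8 when adjusted over the list alone), including Nlrc5, a transcriptional activator of these genes (4.44 ± 0.29), H2-D1 (2.43), H2-K1 (2.33) and the immunoproteasome gene Psmb9 (2.26); camera gave an adjusted p of 1.10e-08, and adjusted p = 0.248 with an estimated correlation. Of 12 interferon response genes, 4 rose (6 when adjusted over the list alone), namely Usp18 (4.49), Bst2 (2.34), Ifi35 (1.73) and Irf9 (1.66), with camera adjusted p = 1.80e-05, and adjusted p = 0.387 with an estimated correlation. The MYC and ribosome biogenesis list was higher, with 2 of 16 members past the test (5 when adjusted over the list alone), Odc1 (2.02) and Srm (1.64), enzymes of polyamine synthesis (camera adjusted p = 5.49e-04, and adjusted p = 0.401 with an estimated correlation). Glycolysis genes had a median of 0.41 with 0 of 11 past the test (1 when adjusted over the list alone; Hk2 at 1.65, Tpi1 at 1.30), and the list was higher (camera adjusted p = 0.0191, and adjusted p = 0.524 with an estimated correlation). The glycolysis list lost its call without lymphoma 1 (adjusted p = 0.0724), without lymphoma 2 (adjusted p = 0.0758), without _x_at and _s_at probe sets (adjusted p = 0.0659) and with only the sorted lymphoma (adjusted p = 0.340). The stem cell marker list was higher with 2 of 19 members past the test, Mycn (4.35) and Hoxb4 (0.95), and the same 2 when adjusted over the list alone (camera adjusted p = 5.71e-04, and adjusted p = 0.426 with an estimated correlation). Another Mycn probe set was at 0.05 and did not pass. The early T list was higher with Il2ra as its only called member of 15, also when adjusted over the list alone (camera adjusted p = 0.0091, and adjusted p = 0.524 with an estimated correlation). In the sorted lymphoma the medians of the stem cell and early T lists turned to -0.03 and -0.05, against 0.94 and 0.67 in the unsorted tumours.

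Lists of markers of other cells were also higher. The macrophage list had a median difference of 3.10 and was higher (camera adjusted p = 3.06e-05, and adjusted p = 0.426 with an estimated correlation), although Ctss, a lysosomal protease (4.73), was its only called member of 13. The stroma and endothelium list (median 2.83; camera adjusted p = 0.0017, and adjusted p = 0.524 with an estimated correlation) had 0 of 11 members past the test, with Dcn at 5.81 and Col3a1 at 4.12. In the NK and cytotoxic list, granzyme A (Gzma) rose 16.0-fold, 1 of 7 members (camera adjusted p = 8.67e-04, and adjusted p = 0.395 with an estimated correlation). Adjusted over the list alone, 3 macrophage, 4 stroma and 3 NK genes rose. The sorted lymphoma alone had medians against DP thymocytes of -0.12 for the macrophage list and -0.12 for the stroma list, but the called members stayed high there, Gzma at 3.84 (-0.21 against the unsorted tumours) and Ctss at 3.05 (-2.24). In the same array the medians were 0.48 for the NK list, 1.93 for MHC class I, 0.84 for interferon, 0.53 for Notch and 2.94 for STAT5 targets.

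**Figure D3:**
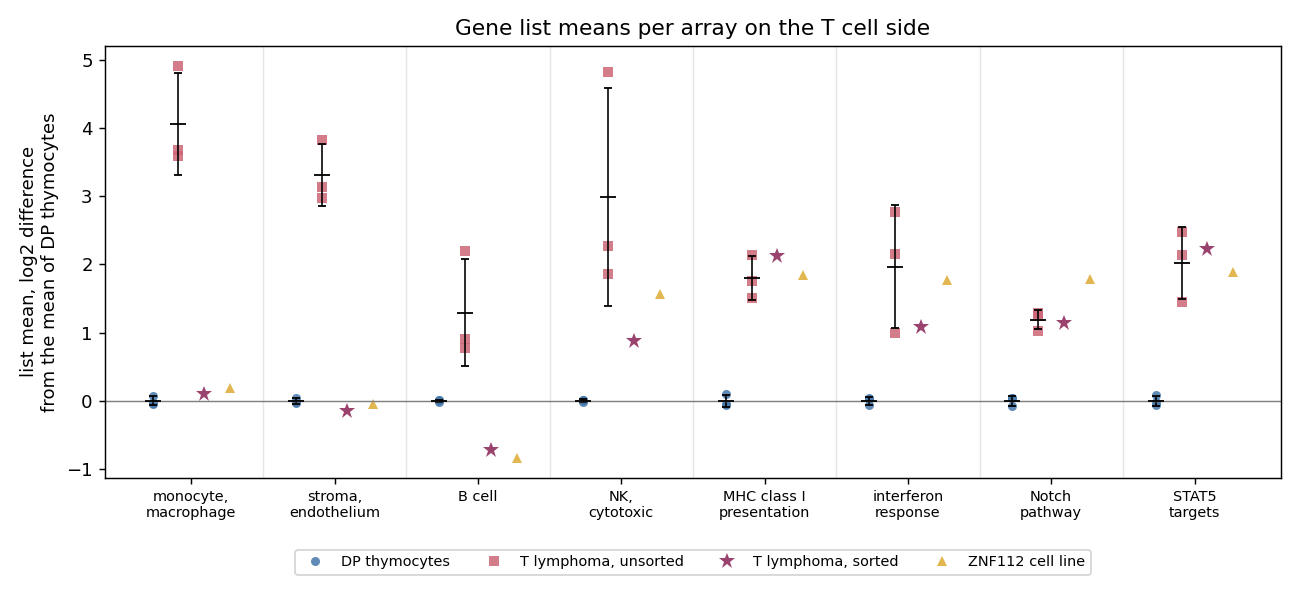
Mean of each gene list in each array of the T cell side, as a log2 difference from the mean of the 3 DP thymocyte arrays (vertical axis); symbols as circles for DP thymocytes, squares for unsorted lymphoma, star for the sorted lymphoma and triangle for the cell line, bars mean and SD. The sorted lymphoma lies near 0 for macrophage and stroma markers and with the unsorted lymphomas for MHC class I, Notch and STAT5 genes.

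The other lists did not pass by camera between T lymphoma and DP thymocytes. Of the 14 that did, 11 also passed by fry, and the glycolysis, macrophage and stroma lists did not (fry adjusted p = 0.189, 0.0760 and 0.109). Replication genes had a median of -0.27 (0 of 18 called, camera adjusted p = 0.106; largest Ccne2 at -1.44) and mitosis genes a median of 0.04 (0 of 16, adjusted p = 0.678; Cdk1 at 0.56). Itgae (4.73) and Itgb7 (2.94), which pair as an integrin that binds E-cadherin, rose and Cxcr4 fell by 1.00 in the homing list (adjusted p = 0.0907). Bcl2, an inhibitor of cell death, rose by 2.34 and its relative Bcl2l1 fell by 1.39 (adjusted p = 0.777). The CDK inhibitors Cdkn2b and Cdkn1a rose by 3.78 and 2.65 while Rb1 fell by 0.96 (adjusted p = 0.799, median -0.04, mean 0.52). In the lymphoid priming list the interleukin-7 receptor gene Il7r (4.14) and Notch1 rose, and Satb1 and Rag1 fell (adjusted p = 0.509). Egr1 fell in the feedback list (adjusted p = 0.126) and, with Zfp36 (-2.27), in the immediate early list (adjusted p = 0.452). Granulocyte, B cell, erythroid and megakaryocyte lists had 0 calls (adjusted p = 0.0867, 0.271, 0.740 and 0.509), with S100a8 at 2.91, H2-Aa at 3.22, Car2 at -2.90 and Vwf at 1.82. Adjusted over the list alone, 3 immediate early genes rose and 5 fell, 1 BCL2 family gene rose and 2 fell, and 2 CDK inhibitor and tumour suppressor genes rose and 3 fell. Fgfr1 (0.41 ± 0.38) and Zmym2 (-0.62 ± 0.27) did not pass (limma, Benjamini-Hochberg adjusted p = 0.580 and 0.210); whether their probe sets lie in the fused parts was not checked. Kit (1.99), Flt3 (0.50), Cd44 (-0.06) and Plcg1 (0.10) did not pass either. Of the 59 named genes called, 45 passed in each of the 7 fits without 1 array; Arap2, Rag1, Runx3, Egr2, Hoxb4, Il7r, Bcl2l1, Rb1, Bst2, Irf9, Itgb7, Cxcr4, Zfp36 and Ptcra did not. The number of calls was 1826 when only these 7 arrays entered the fit, 1572 without the sorted lymphoma, 303 with it as the only lymphoma, and between 383 and 399 without any 1 of the DP arrays. With it as the only lymphoma, Egr1, Cd4, Satb1, Rag1, Egr2, Hoxb4, Il7r, Srm, Bcl2l1, Rb1, Psmb9, Bst2, Irf9, Itgb7, Cxcr4, Zfp36, Ctss and Ptcra did not pass. All 18 kept their direction and 15 at least 50% of their log2 change, with a SE 1.03 to 1.60 times as large from 1 array: Egr1 was at -4.28 ± 0.89 (-4.06 ± 0.57 over the 4 lymphomas), Irf9 at 1.99 ± 0.45 (1.66 ± 0.30) and Itgb7 at 3.90 ± 1.05 (2.94 ± 0.72). Bst2 (1.11 ± 0.57 against 2.34 ± 0.50), Zfp36 (-1.12 ± 0.64 against -2.27 ± 0.52) and Ptcra (0.95 ± 0.52 against 2.27 ± 0.50) kept less than 50%. Not called were other tested probe sets of Arpp21 (-1.66 to -1.22), Il7r (3.67), Bcl2l1 (-0.75) and Rb1 (-0.60).

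The sorted lymphoma was set beside the 3 unsorted ones, since the series included it to see what sorting does to expression. Several genes of other cells were much lower in the sorted tumour. Decorin (Dcn), a matrix protein, was lower by -7.58 ± 0.45, Serping1 by -6.54, clusterin (Clu) by -6.38, the MHC class II gene H2-Ea by -6.60 and Glycam1, a mucin of lymph node vessels, by -5.89. Of 12797 genes, 8 were higher and 76 lower (limma, Benjamini-Hochberg adjusted p under 0.05); the largest rises were in Morrbid (2.67), Mturn (2.43), Sfxn3 (2.37), Acvr2b (2.25) and Akap5 (2.17). In the stroma list 4 of 11 fell (8 when adjusted over the list alone), among them Col4a1 (-5.62), Col3a1 (-5.58) and Bgn (-4.68), and the median was -4.64 (camera adjusted p = 2.13e-14, and adjusted p = 0.193 with an estimated correlation). The macrophage median was -4.34, with Lyz2 lower by -4.55 as 1 of 13 (9 when adjusted over the list alone; camera adjusted p = 2.21e-11, and adjusted p = 0.558 with an estimated correlation). B cell (-2.06, 1 of 13 called, H2-Ab1 by -4.59) and NK lists (-2.23) were lower too (camera adjusted p = 1.17e-05 and 0.0066, and adjusted p = 0.558 for both with an estimated correlation). Of the stem cell markers, Fgd5 fell by 2.03 (1 up and 6 down when adjusted over the list alone), and 10 of the 26 lists passed camera in all, 1 of them higher, while by fry only the stroma list passed (adjusted p = 0.0027). For Dcn, Serping1, Glycam1, Fgd5, Col4a1, Col3a1 and Bgn the sorted array lay under the filter level of log2 6.33, so the size and order of these falls are uncertain. Il2ra, Notch3, Dtx1, Myc and Notch1 had differences of 0.27, 0.23, 0.92, 0.31 and 0.30, with 0 past the test. Only 1 array was sorted, so these values compare tumours as well as the sort; with the 4 lymphoma arrays alone limma called 0 genes, with 1281 at an unadjusted p under 0.05 and a smallest adjusted p of 0.101. Leaving out unsorted lymphoma 2 gave 248 calls and leaving out unsorted lymphoma 3 gave 40, and Sfxn3, Acvr2b, H2-Ea, Serping1, Glycam1, Fgd5, Lyz2 and H2-Ab1 lost their calls in at least 1 of the 3 such fits. Other tested probe sets were not called for Dcn (-0.76), H2-Ea (-3.68), Col3a1 (-1.52), Col4a1 (-3.27), H2-Ab1 (-4.48 and -3.71), Morrbid (2.33) and Acvr2b (0.03 and 0.61).

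LSC were compared with HSC, normal cells of the same sorting phenotype. Several T cell genes and the cytokine and granzyme genes Ifng and Gzma rose in LSC, and several stem cell and myeloid genes fell. Ifng, which encodes interferon gamma, rose by 8.85 ± 1.66, granzyme A (Gzma) by 7.88 ± 0.31, Ctla4 by 7.85 ± 0.77, Il2ra by 7.71 ± 0.28, Ddc by 7.14 and the kinase Camk4 by 7.08. Trgv1 and Trgv4 rose by 6.62 and 6.35 and Tubb2b by 5.93. The stem cell factors Hlf and Mecom were lower by -5.81 ± 0.27 and -5.09 ± 0.91, neutrophil elastase (Elane) by -5.06 and the erythroid factor Klf1 by -4.67. In all, 518 genes rose and 795 fell among 12797 (limma, Benjamini-Hochberg adjusted p under 0.05), with 484 and 744 by 2-fold or more. In the simulation with each group's own spread, false calls outnumbered true ones for this comparison, so its adjusted p-values can be too low. The Y-linked gene Eif2s3y was higher by 8.09 (11.8 ± 0.30 against 3.68 ± 0.19, SD, n = 2 each); per the labels the HSC came from female mice, which lack this gene. Other large falls were in the immunoglobulin genes Igkv15-103 (-7.27) and Ighg3 (-6.59), Bex1 (-5.81), Adgrl4 (-5.28), the eosinophil granule gene Prg2 (-5.15) and the platelet chemokine Ppbp (-4.68). Igkv15-103, Ighg3 and Prg2 were higher in HSC 1 (12.1, 13.7 and 13.3) than in HSC 2 (10.5, 10.9 and 9.70). Whether mature cells in the HSC sort gave these falls was not tested. For 15 of these 20 genes, all but Gzma, Prg2, Elane, Ppbp and Klf1, both arrays of the lower group lay under the filter level of log2 6.33, so the size and order of their changes are uncertain. The size is uncertain for the same reason for 14 further genes named below (Cd3g, Cd3d, Cd2, Zap70, Themis, Cd8a, Lef1, Fas, Cdkn2b, Csf3r, Vpreb1, Epor, Gp5 and Gp9). Ddc (0.51) and Camk4 (0.83 to 3.14) had other tested probe sets that were not called. These calls depend on the fit of all 12 arrays. With the 4 arrays alone, where fewer arrays and the groups' own spread enter, limma called 0 genes. In that fit 1535 genes had an unadjusted p under 0.05 (640 by chance), and the smallest adjusted p was 0.0529. Array weights gave 103 calls. Leaving out an LSC or HSC array leaves 1 array in that group, whose own deviations then count as the group's effect. The higher number of calls without an LSC array is therefore no sign of a stronger result.

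**Figure D4:**
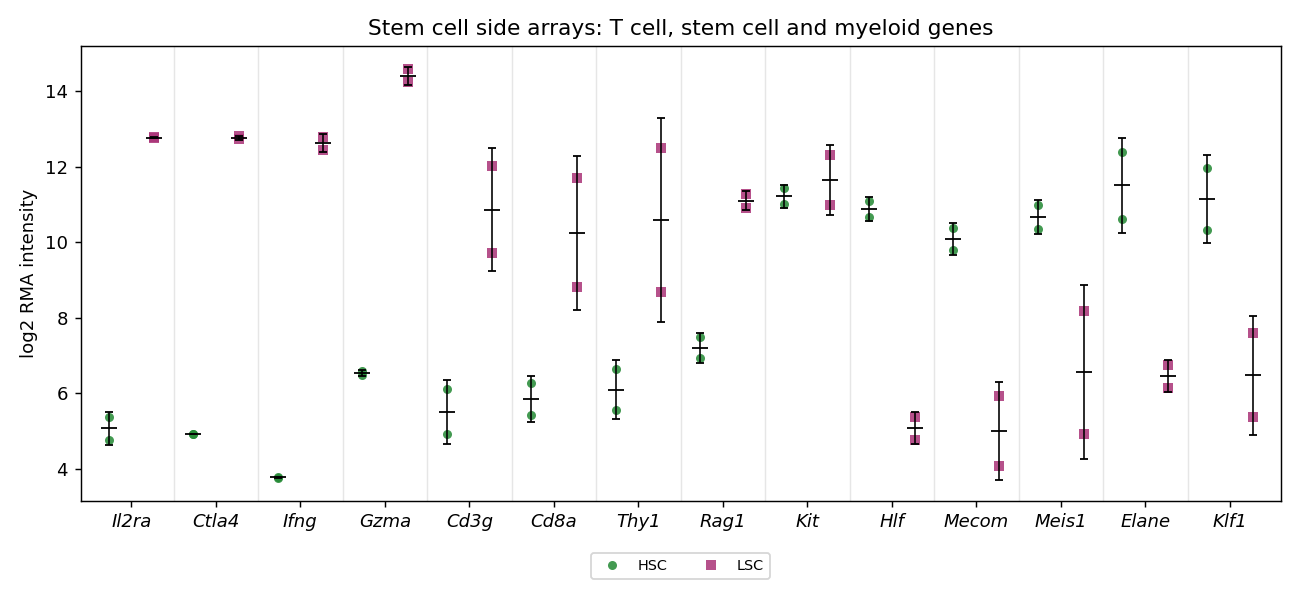
Log2 RMA intensity (vertical axis) of 14 genes in the HSC (circles, n = 2) and LSC (squares, n = 2) arrays, with mean and SD as bars. Il2ra, Ctla4, Ifng and Gzma are high in both LSC arrays, while Cd8a (8.81 and 11.7) and Thy1 (8.67 and 12.5) differ between them.

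Of 15 T cell receptor genes, 8 rose and 0 fell (11 and 0 when adjusted over the list alone), led by the CD3 chains Cd3g (5.35 ± 0.68) and Cd3d (5.03), Cd2 (4.21) and the kinase Zap70 (3.00). Of 15 double-positive genes, 9 rose (10 when adjusted over the list alone), with Themis (5.90 ± 0.49), the T lineage factor Bcl11b (5.48), Thy1 (4.50) and Cd8a (4.41) highest; Rag1 rose by 3.89 ± 0.24 and Cd4 was at -0.17. Among 14 T lineage factors 3 rose, Bcl11b, Lef1 (3.81) and Ets1 (2.62), also when adjusted over the list alone. These 3 lists were higher (camera adjusted p = 2.22e-07, 5.34e-09 and 0.0015, and adjusted p = 0.234, 0.193 and 0.235 with an estimated correlation). Of 19 Notch genes 1 rose and 1 fell, and the list passed by fry but not by camera (fry adjusted p = 0.0051, camera adjusted p = 0.275): Igf1r was lower by -3.26, while Notch1, Notch3 and Dtx1 had differences of 0.08, 1.04 and 1.08 (limma, Benjamini-Hochberg adjusted p = 0.891, 0.120 and 0.209). STAT5 targets were higher, with 4 of 12 past the test (8 when adjusted over the list alone), Il2ra, Socs3 (3.97), Socs2 (3.00) and Cish (2.03), at camera adjusted p = 5.85e-06, and adjusted p = 0.234 with an estimated correlation. CDK inhibitors and tumour suppressors were higher, with 6 of 13 (9 when adjusted over the list alone), including Cdkn2b (5.51), Cdkn1a (2.98), Cdkn1b (2.06) and Trp53inp1 (1.96), at camera adjusted p = 1.87e-07, and adjusted p = 0.136 with an estimated correlation. Other tested probe sets of Cdkn1b (-0.18), Trp53inp1 (0.70) and Lef1 (0.63) were not called (limma, Benjamini-Hochberg adjusted p = 0.928, 0.631 and 0.519), and those of Zap70 were at -0.04 and 1.38, with 1.38 called. The NK list was higher with Ifng and Gzma called, 2 of 7 (Klrd1 at -0.25, Prf1 at 0.48 and Nkg7 at 0.67 did not pass), and the homing list with Itgae (5.31), Cxcr3 (3.49) and Cxcr4 (1.41), 3 of 12 (camera adjusted p = 0.0026 and 0.0123, and adjusted p = 0.295 for both with an estimated correlation). Gzmb of the NK list did not pass either, but stood at 10.69 and 10.65 in LSC against 5.44 and 6.40 in HSC.

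Some stem cell and cell cycle genes were lower in LSC. Of 19 stem cell markers 10 fell and Mycn was called higher (11 and 2 when adjusted over the list alone), with Hlf, Mecom and Meis1 (-4.11) lowest (camera adjusted p = 3.66e-04, and adjusted p = 0.295 with an estimated correlation). The direction of Mycn is in doubt: the probe set used was at 4.79 and another at -2.87, both called (limma, Benjamini-Hochberg adjusted p = 2.93e-05 and 0.0023). In the early T list 5 of 15 fell, among them Meis1, Mef2c (-4.01) and Lmo2 (-3.92), and Il2ra rose (8 and 1 when adjusted over the list alone; camera adjusted p = 0.0135, adjusted p = 0.435 with an estimated correlation, fry adjusted p = 0.653). The LSC arrays stood apart here: the mean of the early T list was 9.46 and 9.72 in HSC, 9.48 in LSC 1 and 6.90 in LSC 2, and Meis1 was 8.19 in LSC 1 and 4.93 in LSC 2. The mean of the stem cell list was 8.75 and 8.96 in HSC, 7.76 in LSC 1 and 6.23 in LSC 2. Replication genes (6 of 18 fell, 13 when adjusted over the list alone) included Mcm3 (-2.33), Pola1 (-2.18), Ccne1 (-1.95) and Mcm2 (-1.71). Mitosis genes (7 of 16, 12 when adjusted over the list alone) included Ube2c (-3.08), Plk1 (-2.51), Kif11 (-2.20) and Birc5 (-2.14). The MYC list (4 of 16, 5 when adjusted over the list alone) included Srm (-2.90), Cad (-2.75), Nolc1 (-2.00) and Polr1b (-1.49). These 3 lists were lower (camera adjusted p = 6.80e-07, 3.73e-07 and 9.81e-05, and adjusted p = 0.235, 0.295 and 0.275 with an estimated correlation). The LSC arrays also had the highest beta-actin 3' over 5' ratios. The HSC arrays differed in these genes: the median of the replication and mitosis genes in LSC was -1.06 against HSC 1 and -2.09 against HSC 2.

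Some myeloid markers fell as well: 6 of 11 granulocyte genes (8 when adjusted over the list alone), such as Elane, Prtn3 (-3.68), Csf3r (-3.50) and Mpo (-3.18); 5 of 8 megakaryocyte genes (6 when adjusted over the list alone), such as Vwf (-3.97), Gp5 (-1.93) and Gp9 (-1.75); and 2 of 8 erythroid genes (3 when adjusted over the list alone), Klf1 and Epor (-2.32). Their lists were lower (camera adjusted p = 6.80e-07, 9.81e-05 and 0.0038, and adjusted p = 0.235, 0.235 and 0.275 with an estimated correlation). The LSC arrays stood apart in these lists too. The granulocyte list mean was 9.278 in LSC 1 and 6.596 in LSC 2, against 11.365 and 10.889 in HSC. The erythroid mean was 8.186 in LSC 1 and 5.695 in LSC 2, and the megakaryocyte mean 7.445 and 5.587. Each of these means was lower in both LSC arrays than in either HSC array. Ier2 (-3.90) and Zfp36 (-3.41) fell in the immediate early list, 2 of 14 (camera adjusted p = 0.0055, and adjusted p = 0.323 with an estimated correlation). Macrophage, B cell and stroma lists did not pass (camera adjusted p = 0.284, 0.0638 and 0.473), with 0, 1 (Vpreb1, -1.92) and 0 calls; C1qa was at -3.13 and Col4a1 at -3.24. MHC class I (Nlrc5 at 2.32), interferon (Usp18 at 1.77), glycolysis (Slc2a1 at 3.04) and BCL2 family lists (Fas at 3.85, Bcl2 at 2.04) had 1, 1, 1 and 2 genes that rose but did not pass as lists (camera adjusted p = 0.190, 0.116, 0.494 and 0.145). The lymphoid priming list had 2 rises, Rag1 and Satb1 (2.29), and the feedback list 0 (Egr1 at -2.17, Phlda1 at 2.01), with camera adjusted p = 0.278 and 0.107; by fry the lymphoid priming list passed (adjusted p = 0.0051). The lymphoid priming median was -0.05 and its mean 0.41. Adjusted over the list alone, 2 interferon and 4 BCL2 family genes rose, 2 glycolysis genes rose and 2 fell, and 3 lymphoid priming genes rose and 2 fell. Plcg1 rose by 1.38 ± 0.28, and Fgfr1 (0.56), Zmym2 (1.07), Kit (0.43), Il7r (3.46), Flt3 (-2.31), Cd44 (-2.02), Myc (-1.04), Hes1 (0.10), Ptcra (1.66) and Nrarp (-1.14) did not pass. Of the 75 named genes called, 46 passed in each of the 4 fits without 1 array, and Thy1, Cd8a, Cd2, Zap70, Ifng, Mecom, Meis1, Plcg1 and all 4 mitosis genes named were among the 29 that did not. The others of the 29 were Prg2, Igf1r, Mef2c, Lmo2, Cish, Mcm3, Pola1, Mcm2, Nolc1, Polr1b, Trp53inp1, Usp18, Cxcr3, Zfp36, Mpo, Vpreb1 and Vwf. Nolc1 (-1.46 and -1.17), Kif11 (-1.45 and -0.97) and Plcg1 (0.26) also had probe sets that were not called. The early T, stem cell, homing, immediate early, erythroid and NK lists also lost their calls in at least 1 of these fits.

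Changes in both compartments overlapped. Of the genes tested, 100 rose in both comparisons where independent lists would share 17.4 (Fisher's exact test, odds ratio 8.63, p = 4.75e-49), and 49 fell in both against 25.3 (odds ratio 2.14, p = 8.33e-06). Trgv1, Trgv4, Il2ra, Ddc, Ctla4, Casp4 (2.66 in LSC), Drc1 (3.63 in LSC), Socs2, Cish, Cdkn2b, Itgae and Gzma rose in both, and Bex1, Ugt8a (-3.49 in LSC, and -0.18 without a call in another probe set) and Zfp36 fell in both. Genes that moved apart numbered 31 higher in lymphoma and lower in LSC, where 26.8 would be shared (odds ratio 1.18, Fisher's exact p = 0.362). Another 33 went the other way, where 16.5 would be shared (odds ratio 2.17, Fisher's exact p = 1.57e-04). The excess of genes lower in both was therefore no larger than that of genes lower in lymphoma and higher in LSC. The counts higher and lower in both were 0 and 0 with only the arrays of each comparison, 15 and 5 with array weights, and 60 to 185 and 18 to 155 on leaving out 1 array. The comparisons share 1 estimate of the spread per gene and genes are not independent, so the expected counts are no exact chance level, and the 4 p-values are not corrected for their number. Carry-over of lymphoma cells into the LSC sort, weighed below, would also put genes among those higher in both. It could not be told apart from expression by the LSC themselves.

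**Figure D5:**
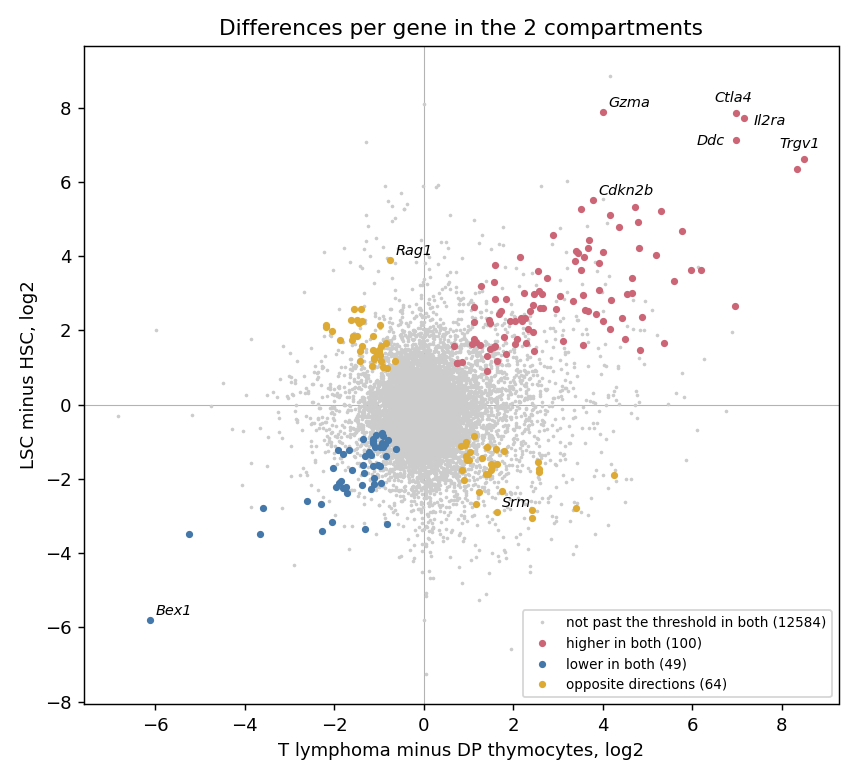
Each point is a gene, placed by its log2 difference between T lymphoma and DP thymocytes (horizontal axis) and between LSC and HSC (vertical axis). Coloured points passed the test in both: 100 higher in both, 49 lower in both and 64 in opposite directions; 12584 genes did not pass in both.

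The difference of the 2 effects was tested directly. It passed for 1136 genes, 676 with a higher and 460 with a lower log2 difference between T lymphoma and DP thymocytes than between LSC and HSC (limma, Benjamini-Hochberg adjusted p under 0.05). The largest positive differences were in Ighg3 (8.53), the granule and liver-type genes Hp (7.37) and Fbp1 (7.35), Igkv15-103 (7.33) and Igkv8-30 (7.20). The largest negative ones were in Camk4 (-8.37), Eif2s3y (-8.07), Tdrp (-8.00), Themis (-6.76) and Cd5 (-6.52). For all of these but Fbp1 and Igkv8-30, at least 1 of the 4 groups lay under the filter level of log2 6.33 in every array, so their size and order are uncertain. In the sorted lymphoma Hp and Igkv8-30 stood at 5.90 and 6.80, near their levels in DP thymocytes (5.63 to 5.88 and 6.33 to 6.55). Dtx1 (3.84), Myc (3.30) and Notch1 (1.56) differed, Il2ra (-0.54) did not (limma, Benjamini-Hochberg adjusted p = 0.0076, 0.0032, 0.0280 and 0.370). Another probe set of Dtx1 was at -0.31 and was not called. The count was 311 with array weights, between 446 and 464 without any 1 of the DP arrays, 653 without unsorted lymphoma 2, and 2229 and 2444 without LSC 1 and LSC 2. Of the 70 named genes called, 42 passed in each of the 11 fits without 1 array. Among those that did not were Notch1, Zmym2, Cd4, Thy1, Ppbp, Hp and Igkv8-30. The LSC comparison, with its many false calls in the simulation, enters this difference, which was not simulated.

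The ZNF112 cell line was set beside the 4 T lymphomas. Igf1r, a growth factor receptor and Notch target, was higher by 4.98 ± 0.71, the Notch target Hey1 by 4.80 ± 0.76, and Smo, the transducer of Hedgehog signals, by 4.19. The Notch list did not pass (median -0.04, 2 of 19 called, 3 when adjusted over the list alone, camera adjusted p = 0.294), with Dtx1 at -1.67 and Nrarp at -0.63. The coreceptor genes Cd8b1 and Cd4 were lower by -6.03 ± 1.01 and -3.44 ± 0.59, and Trgv4 by -5.27. Of 12797 genes 69 were higher and 79 lower (limma, Benjamini-Hochberg adjusted p under 0.05). The other large rises were in Gpt2 (5.03) and Slc7a3 (4.43), and the other large falls in AW112010 (-6.34), the immunoglobulin heavy chain gene Ighm (-6.00) and Ifi209 (-5.29). The cell line lay under the filter level of log2 6.33 for AW112010, Cd8b1, Ifi209 and Itga4 and all 4 lymphomas did for Slc7a3, so the size and order of these changes are uncertain. Replication, mitosis and MYC lists were higher with medians of 1.20, 1.15 and 1.04 and 0 members past the test (7, 0 and 2 when adjusted over the list alone; camera adjusted p = 4.53e-09, 2.44e-06 and 3.40e-05, and adjusted p = 0.478, 0.642 and 0.598 with an estimated correlation). Macrophage and stroma lists were lower with medians of -3.04 and -3.13 (camera adjusted p = 2.81e-04 and 0.0039, and adjusted p = 0.642 for both with an estimated correlation), as were homing (Itga4 at -4.66), B cell, lymphoid priming and double-positive lists (camera adjusted p = 0.0050, 0.0322, 0.0261 and 0.0188, and adjusted p = 0.598, 0.823, 0.478 and 0.642 with an estimated correlation). Adjusted over the list alone, 3 homing, 1 B cell, 4 lymphoid priming and 6 double-positive genes fell. The double-positive list had a median of 0.03 and a mean of -1.09. For macrophage, stroma and B cell markers the sorted lymphoma stood near the cell line, with list means of 6.80, 6.19 and 6.90 against 6.90, 6.29 and 6.78. The lower values of these lists are therefore against the unsorted tumours. By fry 0 of the 26 lists passed (smallest adjusted p = 0.0810). Dusp4 (3.25) and Mycn (1.53) rose and Pfkp (-3.36) fell; Il2ra (-0.28), Notch1 (0.22), Notch3 (-0.93), Cd8a (-4.43) and Il7r (-4.79) did not pass. A single array stands for the cell line; with only the 5 arrays compared limma called 4 genes, with array weights 1834, 68 without unsorted lymphoma 2 and 290 without the sorted lymphoma. Hey1, Smo, Cd8b1, Ighm, Ifi209, Cd4, Mycn, Dusp4, Pfkp and Itga4 lost their calls in at least 1 of the 4 fits without 1 lymphoma, as did the double-positive and B cell lists. Other tested probe sets were not called for Cd4 (-1.14), Mycn (-0.16), Ifi209 (-1.44), Pfkp (-2.56 and -0.56) and Itga4 (-2.76 and -2.21).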

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

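The count of splits and the share of genes kept in the sorted lymphoma were planned; the tests on the macrophage, stroma, MHC class I and interferon lists, on carry-over, on 3' ends and on single LSC and HSC arrays were chosen only after the result was seen, and the rules of the tests on carry-over, on 3' ends, on MHC class I and interferon and on single arrays were also revised after their first outcome. The shares of lymphoma levels on the deposited intensities were added later still. The intervals in this section were taken over genes, which are not independent replicates. They hold no variation between animals or tumours and can be too narrow.

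Of the 35 splits of the 7 arrays into 4 and 3, 1 (the real one) gave as many calls as T lymphoma against DP thymocytes. No share below 1 in 35 is possible, and chance can be excluded only by the narrow margin of 838 calls against 829 in the next split. That split set the 3 unsorted lymphomas against DP thymocytes plus the sorted lymphoma, which is also unsorted against sorted arrays. The count of calls therefore hardly separates lymphoma against normal from unsorted against sorted cells. Of 874 genes higher in the unsorted lymphomas than in DP thymocytes, 47.5% (95% interval 44.1 to 50.9) kept at least 50% of their log2 change in the sorted lymphoma, and 218 lay at or below DP thymocytes there, so other cells in the tumours and a change of the tumour cells cannot be told apart for the set as a whole. For the macrophage and stroma genes the higher of the medians in the sorted lymphoma was -0.12, consistent with RNA of macrophages and stroma in the unsorted tumours, although Ctss, the only macrophage gene called over all 4 lymphomas, stood at 3.05 there (4.73 over the 4). For MHC class I the median was 1.93 in the sorted lymphoma (1.82 in the unsorted ones), which goes against other cells as its source, and for interferon 0.84 (2.04); with 1 sorted array neither can be told apart. Of the 431 genes called higher over all 4 lymphomas, 95.6% kept at least 50% of their change, but that set was chosen with the sorted array in it.

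T cell genes were higher on balance in LSC than in HSC (43 genes, median 1.76). Carry-over of lymphoma cells into the LSC sort would need each abundant lymphoma gene at a similar share of its lymphoma level, counted above the HSC level. Between the sides, normalized apart, only shares relative to Il2ra can be read: Il2ra stood at 57.9% and 59.2% in the LSC arrays on the deposited intensities, but at 138% and 139% with each array divided by its median, more than the 100% that carry-over can reach. Dtx1 stood at 0.717% and 0.863% as deposited, yet with divided arrays only 10.6% of 47 genes (5 genes, 95% interval 3.55 to 23.1; 6 genes as deposited) lay below 10% of the Il2ra share in both LSC arrays. Taken singly, 22 of the 47 genes did in LSC 1 and 5 in LSC 2 (22 and 6 as deposited), against 0 between lymphoma arrays. The median share was 7.53% and 26.7% as deposited (18.1% and 66.2% with divided arrays). These values go against carry-over as the whole cause, but the bound of 25% in both arrays was not met. RNA quality leaves this open too: the 3' over 5' ratio of beta-actin was 13.6 in LSC 1 and 9.82 in LSC 2, but that of Gapdh 7.84 and 8.13. Carry-over and T cell gene expression by the LSC themselves therefore cannot be told apart. A shift toward 3' ends cannot be told apart either: the median stood at percentile 100 of random lists matched on the HSC level (1st to 99th percentile -0.16 to 0.27), but the match holds neither the position of the probe sets nor the length of the transcripts, and the lists ignore the correlation between genes. The Y-linked gene Eif2s3y was 11.98 and 11.56 in LSC and 3.55 and 3.82 in HSC, so the sex of the cells differed along with the groups. Effects of sex and of disease state cannot be told apart in this comparison and were not tested.

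Replication and mitosis genes were lower on balance in LSC than in HSC (34 genes, median -1.57). Their median stood at percentile 0 of random lists matched on the HSC level (1st to 99th percentile -0.61 to 0.20), but a shift toward 3' ends cannot be told apart, with the same limits of the match. Against a single odd LSC array, the medians were -1.68 (95% interval -1.98 to -1.24) in LSC 1 and -1.78 in LSC 2. An odd HSC array cannot be told apart, since the LSC median was -2.09 against HSC 2 but -1.06 (95% interval -1.35 to -0.87) against HSC 1. A cell mixture that differs between LSC and HSC was not tested.

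Of 98 values of named genes and lists in the 4 lymphomas, 6 had an array far from the others, where chance gives about 1 in 20. Trgv1 was 14.05 in lymphoma 2 (others 14.25 to 14.28), Iigp1 13.64 in lymphoma 1 (12.80 to 12.87) and Bcl6 9.18 in lymphoma 2 (8.14 to 8.29). Bcl2l1 was 10.35 in lymphoma 3 (11.21 to 11.34), Rb1 11.60 in the sorted lymphoma (10.96 to 11.03) and Itgb7 9.09 in lymphoma 3 (11.82 to 12.27).

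The lymphoma effect and the LSC effect differed by a limma test of the difference for 1136 of all 12797 genes (8.88%). Among 56 named genes, 35 did, a share that does not stand for other genes: 10 of the 56 (all of which differed) were named for the size of this difference, and 27 (17 differed) for a large change in a comparison. Of the 19 genes fixed in advance, 8 differed. Among them Notch1, Zmym2, Cd4 and Thy1 lost their call in at least 1 fit without 1 array. Higher in the lymphoma comparison were Trgv1 (1.89), Casp4 (4.30), Iigp1 (4.93), Plac8 (6.93), Casp1 (5.05), Notch1 (1.56), Dtx1 (3.84), Myc (3.30), Hp (7.37), Fbp1 (7.35), Igkv15-103 (7.33), Igkv8-30 (7.20), Ighg3 (8.53), Hlf (5.82), Adgrl4 (6.51), Mecom (6.48), Elane (5.12), Ppbp (4.89) and Klf1 (4.81). Lower there were Cd5 (-6.52), Cd6 (-4.90), Tdrp (-8.00), Dgkeos (-4.70), Nhsl1 (-3.61), E2f2 (-3.32), Eif2s3y (-8.07), Gzma (-3.88), Camk4 (-8.37), Tubb2b (-5.61), Themis (-6.76), Zmym2 (-1.69), Cd4 (-2.71), Cd8a (-5.71), Thy1 (-5.57) and Rag1 (-4.65). Other tested probe sets of Dtx1 (-0.31), Nhsl1 (0.10) and Zmym2 (-0.14) were not called.

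By camera, 18 lists differed between the effects. Medians of the difference were negative for T cell receptor genes (-4.35), double-positive genes (-3.97), T lineage factors (-3.02), kinase feedback genes (-0.64) and CDK inhibitors and tumour suppressors (-1.43). They were positive for early T (2.38), stem cell (3.28), replication (1.16), mitosis (1.87), MYC (1.58), MHC class I (1.70), interferon (0.82), granulocyte (3.86), macrophage (4.50), B cell (1.70), erythroid (2.43), stroma (3.86) and megakaryocyte genes (2.18). Erythroid and megakaryocyte medians were 0.14 and 0.09 in the lymphoma comparison and -2.16 and -1.85 in the LSC comparison, so their differences come from the LSC side. Macrophage and stroma medians were 3.10 and 2.83 in the lymphoma comparison, but -0.12 for both with only the sorted lymphoma, 1 array. Early T and stem cell medians were 0.50 and 0.90, but -0.05 and -0.03 with that array. The lymphoma part of these differences therefore rests on the unsorted tumours. The early T, kinase feedback, interferon, macrophage, B cell, erythroid and stroma lists lost their calls in at least 1 of the 11 fits without 1 array. With an estimated correlation 0 of these lists passed, the smallest adjusted p being 0.0922. By fry 13 of the 18 passed, all but kinase feedback, interferon, macrophage, B cell and stroma, and so did the Notch and lymphoid priming lists. Sizes rest on background for 31 of the 70 named genes called in this test, in which at least 1 of the 4 groups lay under log2 6.33 in every array.

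Among 4887 tested probe sets with no gene name, outside the comparisons of genes, limma called 654 between T lymphoma and DP thymocytes (123 higher, 531 lower) and 249 between LSC and HSC (140 higher, 109 lower).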

How the results depend on the processing

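The fit with only the sorted lymphoma was chosen after the result was seen; the other alternatives were planned. With only the arrays compared, limma called 1826 genes for T lymphoma against DP thymocytes (838 in the fit of all 12 arrays), 0 for LSC against HSC (1313), 4 for the cell line (148), 0 for the sorted lymphoma (84), and 0 and 0 genes higher and lower in both compartments (100 and 49); 1535 and 1281 genes had an unadjusted p under 0.05 in the fits with 0 calls. Fewer arrays and the groups' own spread enter these fits. With array weights the counts were 4681, 103, 311 for the difference of effects (1136), 1834, 948, 15 and 5. With every probe set tested they were 1436, 2123 and 1795 for the 3 larger comparisons, and 151 and 88 for both compartments. The mean of all probe sets gave 50 calls and no filter 53 for the sorted lymphoma, and the filter at the 75th percentile 90 for the cell line and 26 lower in both compartments. Only the sorted lymphoma gave 303 calls against DP thymocytes, with list medians turned to -0.0532 (early T), -0.0264 (stem cell), -0.12 (macrophage) and -0.12 (stroma). The cause of these changes was not tested.

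Leaving out 1 array gave 383 to 1572 calls for T lymphoma against DP thymocytes (without DP 2, without the sorted lymphoma), 774 to 2716 for LSC against HSC (without HSC 2, without LSC 2), 446 to 2444 for the difference, 68 to 290 for the cell line and 40 to 248 for the sorted lymphoma. It gave 60 to 185 genes higher and 18 to 155 lower in both compartments. The kinase feedback median of the difference ran from -1.70 to 0.18 (without LSC 1). The double-positive median for the cell line, 0.03 with a test pointing down, ran from -0.11 (without lymphoma 1) to 0.0539, and was -0.0369 with the mean of all probe sets, -0.0556 with cyclic loess and -0.0182 with array weights; its members go both ways.

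Replicate numbers did not pair the samples: the deviations of arrays with the same number correlated at 0.03, -0.07 and -0.001 between DP thymocytes and T lymphoma and at 0.10 between HSC and LSC, and in 0 of the 3 pairs on the T cell side did an array correlate best with its own number. Both HSC arrays did, which with 2 arrays a group follows from the sign of the correlation. With the replicate number as a block there were 1014 calls for T lymphoma, 822 for LSC, 1005 for the difference, and 74 higher and 29 lower in both compartments. Cyclic loess moved the median of all genes by 0.10 for T lymphoma against DP thymocytes, and 59.8% of the calls were then higher, against 51.4%; changes are read relative to such a shift. Values near the array background limit small changes.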

Other observations

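The tests named here were run for all genes, and the genes were chosen only after the result was seen. Cdkn2a, which encodes the cell cycle inhibitors p16 and p19, stood at log2 11.2, 8.90 and 10.3 in the unsorted lymphomas, 6.12 in the sorted lymphoma, 10.1 in the cell line and 5.75 to 6.22 in DP thymocytes. In the stem cell compartment it was 4.71 in LSC 1, 11.6 in LSC 2 and 3.99 and 4.09 in HSC. Cdkn2a did not pass in either comparison (limma, Benjamini-Hochberg adjusted p = 0.2702 and 0.2470). Smo fell in both compartments, by 3.65 ± 0.55 and 3.50 ± 0.72 (limma, Benjamini-Hochberg adjusted p = 0.0043 and 0.0167), and was 10.7 in the cell line against 10.1 in DP thymocytes.

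The HSC arrays differed in markers of mature cells: C1qa of macrophages was 11.4 in HSC 1 and 6.54 in HSC 2. The immunoglobulin gene Ighg3 was 13.7 and 10.9, Prg2 13.3 and 9.70, and the B cell gene Ms4a1 9.0 and 5.0. Ms4a1 was also 10.7 in unsorted lymphoma 3, and 5.53 to 6.59 in the other lymphomas. Xist, which female cells express from the inactive X chromosome, was 12.7 ± 0.18 in HSC and 7.85 ± 0.12 in LSC (SD, n = 2 each; limma, Benjamini-Hochberg adjusted p = 0.0547), beside Eif2s3y at 3.55 and 3.82 in HSC and 11.98 and 11.56 in LSC.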
